A study of Mus musculus with 4 samples.

How the data were processed

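CHD4, the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex, was mapped by CUT&Tag in mouse cells that the labels call spermatogonial, from C57BL/6 animals. In CUT&Tag an antibody guides a protein A/G-Tn5 transposase to chromatin, so that DNA around the bound protein is cut and tagged for sequencing in place. The labels describe 2 samples with an antibody against CHD4 and 2 with non-specific IgG, numbered 1 and 2 in each group and described as biological replicates. The protocol in the labels starts from digested testes. How spermatogonial cells were separated from other testis cells is not given in the sources used here.

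Per the submitters' processing notes, Trim Galore 0.5.0, Bowtie2 2.2.5 and MACS2 2.1.2 were used with the mouse build mm10. The order of the steps, the treatment of duplicate reads and of reads that map to several places, and the way the replicates were combined are not given in the sources used here. The deposited table is 1 peak list, and its peak names pair CHD4 with IgG. It has no value for any single sample, so the replicates could not be compared with each other and no error between them can be given. Per the file headers the table holds a fold (FC), which is the ratio of the CHD4 signal to the IgG background at a peak summit, and its log2, both from the authors. The deposited columns in the caller's order give −log10 p and −log10 q, although their headers had been lost to a spreadsheet error. A deposited score equals 10 times the −log10 q, without its decimals. The other deposited values are positions, widths, summit offsets, distances to a transcript start and an annotation class for each peak. The largest q in the list was 0.049. A peak's fold and its q are the authors' own values. They were used to describe, rank and filter peaks and to compare groups of peaks, within this list only. Fold and −log10 p also served to recover depth. The headers of 2 numeric columns are values of a peak, so the opening peak of the call was read as a header and is not among the peaks analysed here. Among the gene symbols, 5 had been turned into dates, so genes were matched by their numeric identifiers, of which 99.9% were found in the gene table used here.

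The list holds 2066 summits in 1849 intervals, because 182 intervals have 2 or more summits. The interval was the unit of the main tests of location, chromosomes and fold, and the gene that of the gene list tests; an interval was given the fold and q of its summit of highest fold. Gene names, distances and promoter classes are the authors' annotation, which gives each peak to the gene with the nearest transcript start. Coordinates are mm10, counted from 1. Positions of other genes came from a RefSeq gene table of the mouse assembly GRCm38.p6, whose chromosomes have the coordinates of mm10. It lists 21779 protein-coding genes on the chromosomes used, after 340 genes of any kind that start before 3 Mb on a chromosome other than Y were left out, as these positions mostly belong to unplaced sequence.

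The RefSeq gene table gives neither strand nor transcript starts. Peak location, planned as distance to transcript starts, was therefore tested as distance from an interval's midpoint to either boundary of a protein-coding gene, within 1 kb. The chance level came from 1000 shuffles of the intervals within their own chromosomes, between the outermost annotated genes, with a two-sided permutation p whose smallest possible value is 0.002. Intervals per chromosome were compared with each chromosome's share of annotated span, in place of sequenced bases, by exact binomial tests. The 19 gene lists were tested by two-sided Fisher's exact tests of members named for an interval against all other protein-coding genes. Both families of tests were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was taken as passing. The fold of intervals within 1 kb of a transcript start was compared with that of the others by a two-sided permutation test of the difference in medians with 100000 resamples, with a bootstrap interval from 2000 draws. Shares have exact 95% binomial intervals, and fragment numbers exact 95% Poisson intervals, which cover counting error only. Intervals are not biological replicates and neighbouring ones are not independent, so each p describes this list and not the variation between animals.

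The list states no read depth. Depth was recovered from each summit's deposited fold and −log10 p, on the model that the caller divides the scaled number of CHD4 fragments plus 1 by the IgG expectation plus 1 and takes p from a Poisson distribution. A scale of 0.429 gave whole fragment numbers with 1 solution at all 2066 summits, to within 0.0005 on −log10 p. The best other scale solved 57.5% of 40 sampled summits, and the median over other scales was 0%. On this model the CHD4 library held 2.33 times as many fragments as the IgG library. If the caller's preset mouse genome size had been used, which no source states, they held about 8.17 M and 3.50 M fragments. In 500 summits simulated on the same model the method returned the right fragment number in 100% of cases. This checks the calculation and not whether the model holds for the deposited list.

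The other tests were also checked on simulated data. With no effect planted, 4% of simulated lists gave any chromosome call and 3% of random draws over 21779 genes gave any gene list call. When 20% of members were given a peak on top of chance, a list of 72 genes was called in 99% of 100 draws and a list of 24 genes in 36%.

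The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the closing parts say otherwise. The rule named every NuRD member with a peak, up to 4 members of each other list with the highest fold, the genes of the 10 intervals of highest fold, and the 5 genes with most intervals, where a tie added 1 more. A gene that the rule would name is not reported here. Alternatives were other windows, the upper part of the list by fold, other chance models, gene backgrounds and gene assignments, lists matched on gene length, and −log10 q in place of fold. Base composition, repeat content and replicate overlap were not analysed here, as no genome sequence and no values per replicate were used. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.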

Results

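The peak list gives the places where CHD4 signal was called above IgG in mouse cells labelled spermatogonial, from 2 CHD4 and 2 IgG CUT&Tag samples. The series asks about CHD4 as a regulator of the survival of spermatogonial stem cells, and the design implies the comparison of CHD4 with IgG along the genome. There were 1849 intervals, with a median width of 280 bp and a range from 184 to 1999 bp. The fold of CHD4 over IgG, the caller's own value, had a median of 4.76 and ranged from 1.75 to 13.6. Recovered depth was low: a summit held a median of 27 CHD4 fragments, with quartiles of 20 and 40.8 and a range from 12 to 177, over a median IgG expectation of 1.48 fragments. In 474 intervals fewer than 20 CHD4 fragments supported the peak. The list is 1 call over the replicates, so no peak has a replicate check.

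The strongest interval by fold lay 13.8 kb from the start of Arf6, a small GTPase of membrane traffic, at chromosome 12, 69385995 to 69386429. Its fold was 13.6, from 47 CHD4 fragments over an IgG expectation of 0.554. The next interval was in intron 1 of Kdm1a, which encodes the histone demethylase LSD1 (chromosome 4, 136598368 to 136598954), with a fold of 12.3 from 55 fragments over an expectation of 1. Actn4, an actin cross-linking protein, had an interval of fold 12.2 at 6.13 kb from its start. Tcf4, a basic helix-loop-helix transcription factor, had 1 of fold 11.6 within an intron, and Lamc1, the laminin gamma 1 chain, had 1 of fold 11.3 in intron 1. The other 5 of the 10 highest folds, from 10.8 to 11.1, were given to Tex14, which is needed for the bridges between germ cells, to the uncharacterised transcripts 4930578M01Rik and Gm6712, to Fam161a, and to Phf20, a chromatin reader. The Fam161a interval lay 54.3 kb from the start of that gene and overlapped the long non-coding RNA gene Gm12059. The Tex14 interval overlapped Rnu3b2, a gene for U3, a small nucleolar RNA that the gene table used here lists as small nuclear. Low IgG expectation went with these folds: none of the 10 exceeded 1.11 fragments, and their CHD4 fragments ranged from 32 to 55. At Tcf4, Lamc1, Fam161a and Gm6712 the expectation was 0.346, the lowest of the list and shared by 131 summits. This value is taken as the caller's floor, so these folds do not rest on IgG fragments counted at the summit.

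Tns3, a focal adhesion protein, was named for 8 intervals, the most of any gene, with folds from 3.68 to 6.76. Dlgap1, a synaptic scaffold protein, and Tex14 followed with 7 each. The Dlgap1 intervals lay together inside the gene, 53.3 to 88.9 kb from the transcript start they were assigned to. Txndc2, a thioredoxin of spermatids, Ccnl1, a cyclin linked to splicing, and the transcript D230017M19Rik had 6 each. The Ccnl1 intervals lay 18.4 to 105 kb from the start of that gene, and none overlapped it. Among the D230017M19Rik intervals were those over Gm25360, Gm23472, Gm24497 and Gm25939, genes listed as small nuclear RNA. Of the Txndc2 intervals, 3 lay within the neighbouring gene Rab31, so these assignments do not follow the gene that holds the peak. Of the 7 Tex14 intervals, 6 overlapped a gene listed as small nuclear RNA: Rnu1a1, Gm22068, Rnu3b1, Rnu3b3, Rnu3b4 and Rnu3b2. The interval at Rnu3b1 (chromosome 11, 87443295 to 87444277) had the highest −log10 q of the list, 39.1, with a fold of 10.7 from 147 fragments.

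**Figure D1:**
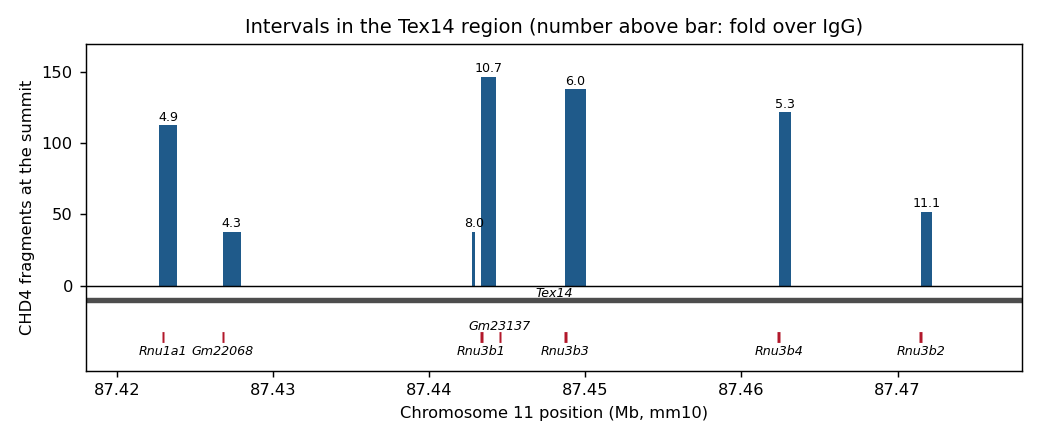
CHD4 intervals in the Tex14 region of chromosome 11 (position in Mb, mm10). Bar height is the number of CHD4 fragments at the strongest summit, bar width is the interval to scale, the number above a bar is its fold over IgG, and the marks under the axis are genes, with Tex14 in grey and genes listed as small nuclear RNA, U3 genes included, in red; 6 of the 7 intervals overlap a red gene.

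CHD4 intervals concentrated at promoters. By the authors' annotation 631 of the 1849 intervals lay within 1 kb of a transcript start, or 34.1% (exact 95% interval 32.0 to 36.3), and 290, or 15.7% (14.1 to 17.4), contained the start. Introns held 493 intervals (26.7%, 24.7 to 28.7) and distal intergenic sequence held 457 (24.7%, 22.8 to 26.7). Exons held 82, the 3′ UTR class 14 and the 5′ UTR class 2. Measured against gene boundaries, 25% of interval midpoints lay within 1 kb of the boundary of a protein-coding gene, against 3.25% ± 0.431 (SD over 1000 shuffles). This was 7.7-fold above chance (two-sided permutation p = 0.002, the smallest the shuffles can give), and the highest shuffle reached 4.87%. The strongest promoters among the named genes were those of 4930578M01Rik, Gm6712 and Phf20, with folds of 11, 10.9 and 10.8, followed by those of Zfp184 at 9.95 and Hdac1 at 9.18. Of the 462 intervals near a boundary, 409 lay within 1 kb of the 5′ end of the gene they were named for. Near its 3′ end, within 1 kb, lay 21, by the authors' strand. Naming by distance to a transcript start favours the 5′ end. Among the 930 intervals of highest fold, 14.8% lay near a boundary, 4.66-fold above chance (permutation p = 0.002). Shuffling only within 50 kb, chosen after seeing the data, lowered the enrichment to 3.71-fold (permutation p = 0.002). Neither kind of shuffle allows for open chromatin that the transposase cuts more readily, and its part in this enrichment was not tested.

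Promoter intervals had more CHD4 fragments than other intervals but a lower fold over IgG. The median fold was 4.32 in the 631 promoter intervals and 4.98 in the 1218 others, a difference of −0.657 (bootstrap 95% interval −0.829 to −0.546; two-sided permutation test, p = 1e-05, the smallest 100000 resamples can give). Promoter intervals had a median of 34 CHD4 fragments against 25 elsewhere, and a median IgG expectation of 2.4 fragments against 1. A peak over a higher IgG expectation needs more CHD4 fragments to pass the q threshold. The higher fragment number therefore does not by itself show more CHD4 at promoters. Dusp6 had a promoter interval and another. At its promoter the fold was 3.1 from 41 fragments over an expectation of 4.98, and 31.5 kb away it was 6.29 from 27 fragments over 1. At Gata4 the promoter interval had a fold of 3.54 over an expectation of 4, and the interval 8.51 kb away in an intron had 5.74 over 0.369. By −log10 q in place of fold, the medians of promoter and other intervals were 2.89 and 2.92, and the difference of −0.0324 did not pass the permutation test (p = 0.76).

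**Figure D2:**
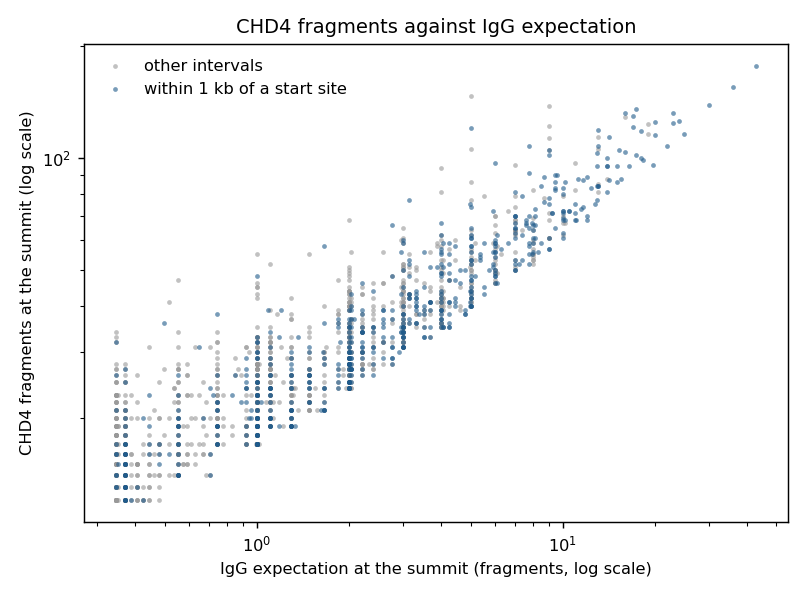
CHD4 fragments at the strongest summit of each of the 1849 intervals against the IgG expectation there, both as fragments on log axes, recovered from the deposited fold and −log10 p. CHD4 fragments are shown before scaling to the smaller IgG library, so the ratio of the axes is not the fold. Blue points are the 631 intervals within 1 kb of a transcript start and grey points the 1218 others; the lower edge of the cloud is the caller's q threshold, and blue points reach farther to the right, with median IgG expectations of 2.4 and 1.

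The intervals named 1517 genes, of which 1329 were protein-coding, or 6.1% of the 21779 in the gene table. Of the 19 gene lists, 2 passed the test. Replication-dependent histone genes were named more often than other genes, at 11 of 64 members (17.2%, exact 95% interval 8.9 to 28.7) against 6.07%, with an odds ratio of 3.21 (Fisher's exact test, adjusted p = 0.015). Hist1h1e and Hist1h2bk, a linker and a core histone, had intervals at their starts with folds of 6.37 and 5.28, and Hist1h1d had 1 of fold 6.25 at 1.77 kb. Both intervals of Hist1h2ah, at folds of 6.37 and 4.79, overlapped transfer RNA genes that lie among the histone genes. Without intervals on small nuclear, transfer and 7S RNA genes, an alternative chosen after seeing the data, the histone odds ratio was 2.56 and no longer passed (adjusted exact p = 0.09). With 1 interval kept per locus of 10 kb, chosen likewise, it was 1.62 (adjusted exact p = 0.51). In the 930 intervals of highest fold, a setting fixed beforehand, it was 2.64 and did not pass either (adjusted exact p = 0.3). Against random lists matched on gene length, as planned, histone genes were named 11.7 times as often. Against lists matched on gene territory, chosen after seeing the data, they were named 5.37 times as often (adjusted permutation p = 0.0019 in both). These lists were drawn gene by gene from all protein-coding genes, so neither comparison allows for named histone genes that lie close together. Olfactory and vomeronasal receptor genes, which are silent in most tissues, were named less often, at 2 of 1461 (0.137%, 0.0166 to 0.494) against 6.53% (odds ratio 0.0196, adjusted exact p = 6.5e-37). These 2 were Olfr1423, at 26.2 kb, and Vmn2r29. Random lists matched on gene length gave 27.4 named genes on average, and lists matched on gene territory 68.2 (adjusted permutation p = 0.0019 in both). All of these tests take the receptor genes as independent, so they do not allow for members that lie close together.

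Among the members of the NuRD complex itself, 2 of 15 had an interval, which did not pass the test (13.3%, exact interval 1.66 to 40.5; odds ratio 2.37, adjusted exact p = 0.4). They were the deacetylase genes Hdac1 and Hdac2, both at the promoter. The Hdac1 interval (chromosome 4, 129528729 to 129529187) had a fold of 9.18 from 27 fragments (exact Poisson interval 17.8 to 39.3) over an IgG expectation of 0.369. The Hdac2 interval (chromosome 10, 36974301 to 36974504) had a fold of 5.84 from 44 fragments over 2.4.

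Of the genes for stem cell self-renewal and undifferentiated spermatogonia, 3 of 27 were named (11.1%, 2.35 to 29.2; odds ratio 1.93, adjusted exact p = 0.4). Dusp6 and Spry4, feedback inhibitors of ERK signalling, had promoter intervals. The interval named for Spry4 (chromosome 18, 38601398 to 38602042) had a fold of 5.11. It lay 0.13 kb from the Spry4 start and overlapped the gene Arhgap26, not Spry4. Nanos3, an RNA-binding protein of germ cells, had an interval 6.8 kb away with a fold of 3.4 from 69 fragments. No member of the spermatogonial differentiation list was named (0 of 13; exact interval up to 24.7%; adjusted exact p = 1), and none of the pan-germ cell and piRNA list (0 of 22; up to 15.4%; adjusted exact p = 0.87). Of 32 meiosis genes, 2 were named (adjusted exact p = 1): Prdm9, the methyltransferase that sets recombination sites, at its promoter with a fold of 3.45, and Meioc, needed for meiotic progression, at 19.4 kb with 5.61. Odf1, a protein of the sperm tail, was the only 1 of 28 spermatid genes (fold 4.98 at 34.7 kb; adjusted exact p = 1).

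Genes of apoptosis and the p53 response were named in 4 of 24 cases (16.7%, 4.74 to 37.4; odds ratio 3.08, adjusted exact p = 0.19), which did not pass the test. Bax and Bbc3, which promote cell death, and Bcl2, which opposes it, had promoter intervals with folds of 4.62, 3.97 and 4.49. Bcl2l1, which encodes the survival factor BCL-XL, had an intronic interval of fold 4.33. The Bcl2 interval rested on 12 fragments, the lowest number found at any summit. Growth factor, PI3K and MAPK signalling genes were named in 5 of 29 cases (17.2%, 5.85 to 35.8; odds ratio 3.21, adjusted exact p = 0.14). The kinase gene Mapk3 and the Ras activator Sos1 had promoter intervals with folds of 4.36 and 6, and Eif4ebp1, a translation repressor, had 1 of fold 6.08 at 1.56 kb. Cell cycle genes numbered 3 of 36 (adjusted exact p = 0.7). Cdkn2b, an inhibitor of cyclin-dependent kinases, had a promoter interval of fold 3.94, and the Cdk6 interval lay 189 kb away. Both Aurkb intervals overlapped transfer RNA genes.

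Retinoic acid pathway genes were named in 2 of 18 cases (adjusted exact p = 0.48). These were Aldh1a2, at its start with a fold of 5.84, and Aldh1a1, in an intron with a fold of 5.2, both enzymes of retinoic acid synthesis. Marker genes of other testis cells were also in the list. For Sertoli cells 3 of 21 were named (odds ratio 2.57, adjusted exact p = 0.32): Gata4, Inhbb and Ctsl. For peritubular myoid, endothelial and macrophage cells 3 of 15 were named (odds ratio 3.85, adjusted exact p = 0.19): Kdr at 11.9 kb, Acta2 at 15.9 kb and Cdh5 at 99.3 kb, none at a promoter. No Leydig cell gene was named (0 of 10; up to 30.8%; adjusted exact p = 1). Among somatic lineage transcription factors 1 of 20 was named (adjusted exact p = 1), Gata6, with a promoter interval of fold 4.75. No Hox gene was named (0 of 39; up to 9.03%; adjusted exact p = 0.36).

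Ribosomal protein genes were named in 8 of 72 cases (11.1%, 4.92 to 20.7; odds ratio 1.93, adjusted exact p = 0.22) and did not pass. Of these, 7 had a promoter interval, and by promoter intervals alone the odds ratio was 4.13 and passed (adjusted exact p = 0.016). Against random lists matched on gene length the 8 named genes compared with 2.46, a ratio of 3.26 that also passed (adjusted permutation p = 0.039). Against lists matched on gene territory, chosen after seeing the data, the ratio was 2.71 and did not pass (adjusted permutation p = 0.066). Rpl5 and Rpl37a had intervals over their starts with folds of 6.72 and 4.77. Rps29 had the highest fold among the ribosomal protein genes, 10.1 from 45 fragments, at an interval 15 kb from its start that overlapped the long non-coding RNA gene Gm31447. Its promoter interval, with a fold of 3.21, also overlapped the 7S RNA gene Rn7s1, and the 3 intervals of Rps14 lay 11.1 to 22.3 kb away. Zinc finger genes were named in 36 of 397 cases (9.07%, 6.43 to 12.3; odds ratio 1.55, adjusted exact p = 0.12), and by promoter intervals alone the odds ratio was 2.05 and passed (adjusted exact p = 0.026). Against random lists matched on gene length or on gene territory they did not pass, with ratios of 1.46 and 1.57 (adjusted permutation p = 0.13 and 0.057). Zfp184, Zfp52 and Zfp583 had intervals over their starts with folds of 9.95, 6.57 and 6.44, and Zfp960 had 1 at 59.2 kb with 6.5.

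**Figure D3:**
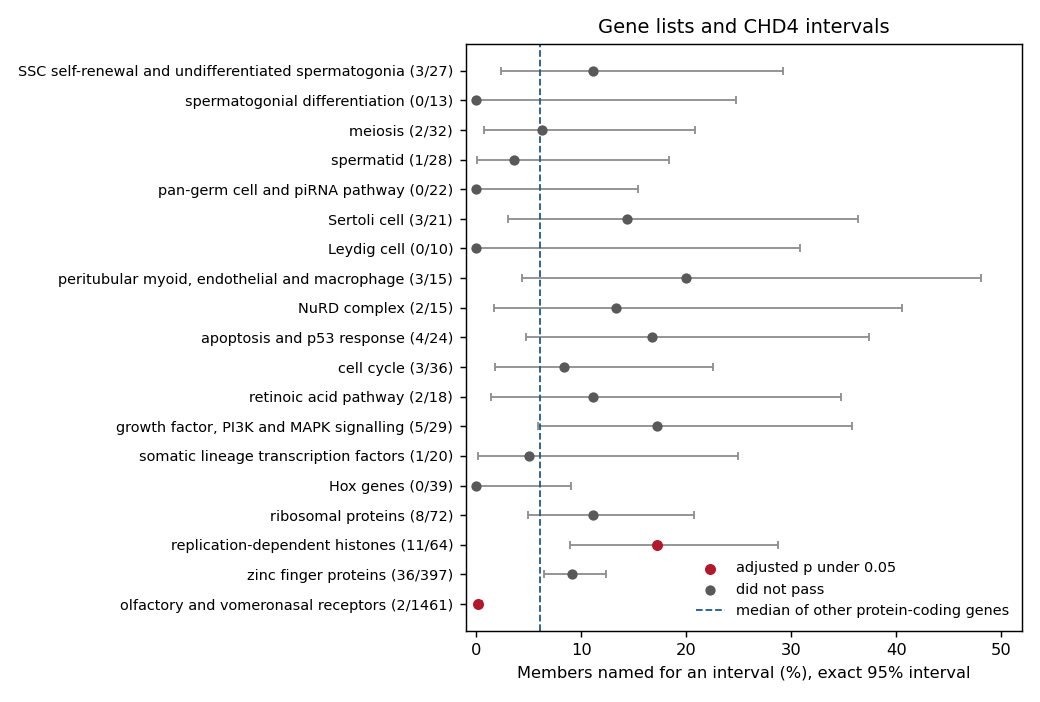
Share of each gene list named for a CHD4 interval, in percent, with exact 95% binomial intervals. Numbers after each name are members named and members in the gene table, red points passed the adjusted threshold, and the dashed line is the median share among genes outside each list; histone genes lie at 17.2% and olfactory and vomeronasal receptors at 0.137%.

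The sex chromosomes carried few intervals. The X chromosome held 19, against 116 expected from its span, a ratio of 0.163 (exact 95% interval 0.0984 to 0.254; exact binomial test, adjusted p = 1.1e-28). Against the number of protein-coding genes the ratio was 0.232 (0.14 to 0.362; adjusted exact p = 1.1e-15). Of the 19, 8 lay at promoters. The X intervals with the highest folds, named after their values were seen, were at Fancb, a gene of the Fanconi anaemia DNA repair pathway, with 9.03, and at Dmd, the dystrophin gene, with 8.71. They held 26 and 25 CHD4 fragments over the lowest IgG expectation of the list, 0.346. The Y chromosome held 1 interval, against 63.1 expected, 26.2 kb from the start of Erdr1. Among the autosomes, chromosomes 7, 10, 11, 17 and 19 lay above expectation by span, with ratios from 1.29 to 1.65, and chromosomes 1 and 14 below it, at 0.704 and 0.686. By gene number, chromosomes 10, 12 and 13 lay above, at 1.34, 1.44 and 1.38, and chromosome 2 below, at 0.767. Only chromosome 10 and the sex chromosomes passed in the same direction under both. Expected numbers spread all 1849 intervals over all 21 chromosomes, so the deficit on X and Y raises the ratio of every autosome. Calls above expectation, that of chromosome 10 included, therefore partly reflect this deficit. Autosomes were not tested against the autosomal rate alone. Much of the Y chromosome is repeated sequence, and how reads that map to several places were treated is not given in the sources used here.

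**Figure D4:**
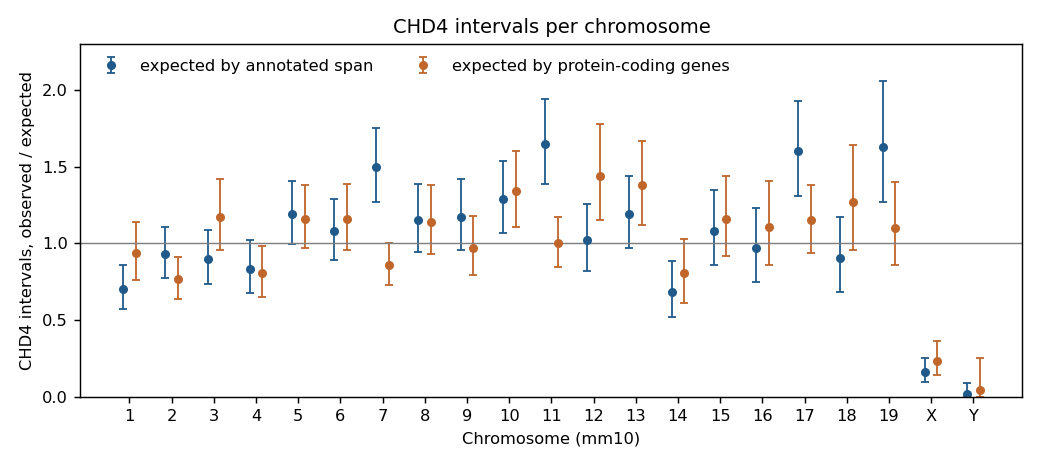
Number of CHD4 intervals on each chromosome divided by the number expected, from annotated span in blue and from protein-coding genes in orange, with exact 95% binomial intervals. The X chromosome lies at 0.163 and 0.232, below every autosome under both.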

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

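The alternatives with summits as the unit, 1 interval per locus of 10 kb, intervals on small nuclear, transfer and 7S RNA genes left out, shuffling within 50 kb, lists matched on gene territory and a fragment ratio without the added 1 were chosen after seeing the data. The others were planned. The enrichment at gene boundaries stayed past its threshold in every setting run, between 2.95-fold (window of 5 kb) and 12.7-fold (window of 500 bp), and at 4.66-fold in the 930 peaks of highest fold. For the main results, 27 alternative values kept their side of the threshold or, for counts of calls, stayed within 1.5 times the main count, 5 fell short and 2 rose above. The number of chromosomes that differed fell from 9 to 4 in these 930 peaks, where fewer intervals were tested. By gene number 6 differed, of which only chromosome 10, X and Y were also among the 9. The number of gene lists that passed, 2 in the main test, was 4 with only promoter peaks, 3 with lists matched on gene length, where ribosomal protein genes gained the call, 7 with all annotated genes as the background, and 1 each with those 930 peaks, with 1 interval per locus and without intervals on small RNA genes. The 7 arise from a background that adds genes other than protein-coding ones, which the lists do not hold. In the settings with 1, the histone genes did not pass (Fisher's exact test, adjusted p = 0.3, 0.51 and 0.09). For single lists, 141 alternative values kept their side, 8 gained the call and 3 lost it. The lower fold at promoters did not pass by −log10 q, with a difference of −0.0324. A test of IgG fragments at promoters as the source of the lower fold is given in the closing part.

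No paired analysis was possible because the list holds 1 call with no values per replicate. For the same reason leaving out a replicate and 50% reciprocal overlap were not run. Filters on repeats and all tests of base composition, with random positions by distance to the transcript start, were not run without a genome sequence. The number of genes limits what the small lists can show: in simulated data a list of 24 genes with 20% of members added was called in 36% of draws, so lists of this size that did not pass are not shown to lack CHD4. The 474 intervals with fewer than 20 fragments have wide counting errors.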

Other observations

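The tests of the immediate-early and co-repressor lists, and the test that joins X copy number with gene number, were chosen after the results were seen. The other tests below were set before their results were seen, on patterns noticed in the list.

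Immediate-early and stress response genes, which are induced within minutes by growth factors or cell stress, were among the most often named groups. Intervals named 19 of 38 such genes (50%, exact 95% interval 33.4 to 66.6) against 6.03% of other protein-coding genes, an odds ratio of 15.6 (Fisher's exact test, p = 8.6e-14). The list was drawn up because genes such as Dusp6 and Ccnl1, which are not in it, had been seen among the named genes, and before peaks of its members had been. Random lists matched on gene length gave 1.52 named genes on average, and lists matched on gene territory, meaning the gene and the gaps beside it shared with its neighbours, gave 2.45 (permutation p = 0.0002 in both, the smallest that 10000 random lists can give). The members included the AP-1 genes Fos, Fosb, Jun, Junb and Jund, the growth arrest genes Btg1, Btg2, Gadd45b and Gadd45g, and the feedback phosphatase gene Dusp1. Most of their intervals lay outside promoters: Fos at 22.9 kb with a fold of 4.8, Jun at 53.2 kb with 5.91, and Btg2 at 3.79 kb with 7.19. Junb, Per1, Zfp36, Dnajb1, Hspa1b and Ccn2 had a promoter interval, and by promoters alone the odds ratio was 7.18 (Fisher's exact test, p = 0.00038). The cells came from digested testes; whether the digestion bears on this pattern was not tested.

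Genes for other co-repressors and chromatin enzymes were also named more often, at 11 of 41 (26.8%, 14.2 to 42.9; odds ratio 5.68, Fisher's exact test, p = 2.4e-05; p = 0.0016 against length-matched lists). The list was drawn up after peaks of 2 members had been seen, and without these 9 of 39 were named (odds ratio 4.64, Fisher's exact test, p = 0.00046; p = 0.011 against length-matched lists). The Polycomb methyltransferase genes Ezh1 and Ezh2 had intervals, at 1.6 kb with a fold of 5.95 for Ezh1, and at 55.6 and 59.3 kb with folds of 3.81 and 4.67 for Ezh2. Members with a promoter interval were 2, the remodeller genes Chd2 and Smarca2, and by promoters alone the list did not pass (odds ratio 1.95, Fisher's exact test, p = 0.28). The intervals of Bcor, Arid1b and Chd7 rested on 12 fragments each, the lowest number found at any summit.

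Genes listed as small nuclear (U3 included), transfer and 7S RNA were overlapped by 46 intervals, against 0.45 on average in shuffles within chromosomes, with 4.72 as their median fold from 54 CHD4 fragments; the authors' annotation gave 33 of them to a protein-coding gene, and for 14 genes that was the only interval. A peak-rich neighbourhood alone was argued against, since shuffling within 50 kb gave 10.7 times fewer overlaps than observed, with 12 as its highest. For background shared with IgG, intervals of the same decile of IgG expectation were compared. Those on small RNA genes had a log2 fold 0.25 higher (permutation p = 0.0001, the smallest possible), set beforehand as evidence against it. This does not decide, since matching sets aside signal shared with IgG and the list holds only intervals that passed over IgG. Without matching, the median IgG expectation was 5 fragments on small RNA genes and 1.29 at other intervals, with median folds of 4.72 and 4.76. Open chromatin that the transposase cuts more readily with any bound antibody than with IgG, and reads shared between copies of these genes, stay open, as neither was tested. Against the same local shuffles, microRNA genes and long non-coding RNA genes also had more intervals than chance, 7 against 0.835 and 282 against 205 (permutation p = 0.002 in both). Pseudogenes had fewer, 3 against 10.5 (permutation p = 0.018), and the 1056 on protein-coding genes did not pass (1.02-fold, permutation p = 0.16). No interval overlapped the 1330 genes listed as small nucleolar RNA, where these shuffles gave 0.643 on average. The permutation p-values of these gene classes were not adjusted for the number of classes compared.

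The X chromosome held 19 intervals (exact Poisson interval 11.4 to 29.7), where the autosomal rate per base gives 128. Fewer genes alone are argued against, as gene number gives 81.8. The single X copy of male cells could account for part: when fragments of autosomal peaks were halved in simulation, 29.5% still passed, which gives 37.6 on the X. That value lies above the interval, which had been set beforehand as evidence against this explanation, but it comes from simulated settings and from the autosomal rate per base, which ignores the lower gene number of the X, so it does not decide. With gene number and copy number together the expectation was 25.3, within the interval. It rests on the same simulated halving and scales all intervals by gene number, so it does not decide either. Silencing of the X in meiotic cells, should the samples hold them, was not tested.

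The lower fold at promoters may come from more IgG fragments at promoters, since a peak with more background passes the q threshold at a lower fold. The difference in median log2 fold was −0.2 between all promoter and other intervals, and −0.02 within deciles of IgG expectation (permutation p = 0.052). The remaining difference lies close to the threshold, so a small one is not excluded. No biological explanation was tested.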
